A study of Brassica oleracea var. capitata with 24 samples.

How the data were processed

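Leaf RNA of cabbage seedlings was measured on 24 single-colour arrays, 4 for each of 6 groups: mock-inoculated and *Xanthomonas campestris* pv. *campestris* (Xcc)-inoculated plants sampled 6, 24 and 48 h after the midvein was inoculated. Per the labels, 500 ng of total RNA was labelled with Cy3 and hybridized to a Brassica array built from expressed sequence tags. There were 2 arrays on each of 12 slides, and each slide held arrays of 1 group only. Neither treatment nor time can therefore be fully told apart from slide in any comparison. The labels do not say whether the replicates of a group are separate plants. All p-values therefore measure the spread between these samples only, part of which may be technical.

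Per the file headers, the scanner files were made with Feature Extraction 10.5.1.1 and hold processed intensity in which the background was subtracted and spatial and multiplicative trends were removed. The authors also deposited a series matrix of normalized log2 values, whose method of scaling its labels leave open. Its values correlate with quantile-normalized log2 intensities centred on each probe's median at 1 or just under in every column, over 91488 probes compared, which settles how they were made. The matrix column medians run from -0.011 (Xcc 6 h replicate 1) to 0.019 (Xcc 24 h replicate 4). The matrix was used only as an alternative source of values.

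Values were read with R 4.3.3 and data.table (version 1.17.8). Control spots were left out, spots marked by the scanner software as non-uniform or as population outliers were set missing, and spots of 1 probe were averaged. The 105072 spots of an array gave 91854 non-control probes. A probe was tested if it lay well above background on all 4 arrays of at least 1 group, which left 27265 probes. Each array's log2 values were scaled by subtracting its 75th percentile. Under 50% of probes were detected on any array, so the percentile was taken over the 12543 probes well above background on all 24 arrays; the percentile over all probes was added as an alternative. Levels in the text are on this log2 scale.

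A linear model with a mean for each of the 6 groups was fitted to all 24 arrays with limma 3.58.1 (lmFit, contrasts.fit, eBayes), which leaves 18 residual degrees of freedom. The median residual SD was 0.463 on the log2 scale. With 4 arrays per group their number limits the precision of every value. There were 8 comparisons: Xcc against mock at each time, the 3 differences between those effects, and mock at 24 h against 6 h and at 48 h against 24 h. A probe counts as changed at an adjusted p under 0.05 (Benjamini-Hochberg, within a comparison). Where no array of a group lay well above background, the change is given as a bound. The bound sets the brighter group's mean over all its replicates against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

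Gene lists were drawn from keywords on the array's descriptions, which name 16589 of the tested probes (60.8%). The 25 lists cover salicylic acid signalling, pathogenesis-related proteins, jasmonate, ethylene, pattern-triggered immunity, indole and aliphatic glucosinolates, phenylpropanoids and lignin, flavonoids and anthocyanins, and abscisic acid and dehydration. They also cover photosynthesis, chlorophyll synthesis, senescence, sugar transport, oxidative stress, heat shock, folding in the endoplasmic reticulum, and early genes of wounding, touch and cold. The last are the circadian clock, auxin, xylem, phloem, epidermis and guard cells, cell division, and housekeeping. Lists were tested with camera in limma with a preset correlation of 0.01, adjusted over the 25 lists of a comparison, and again with the correlation estimated from the data. Lists, comparisons, tests and most alternatives were fixed before the data were examined.

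Genes are named in the report by a fixed rule. For each Xcc comparison these are the 10 largest rises and 10 largest falls among called probes with a name whose 4 against 4 values do not overlap, 1 probe for each name. For each list they are up to 4 called members with the smallest p, or the 1 member with the smallest p when none was called. A set of defence genes fixed in advance, such as *PR1*, and the 5 smallest p of each direction where nothing was called complete the rule. The genes of the mock comparisons, the probes called at both times and 2 further gene sets were chosen after the values were seen.

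Alternatives tried were quantile normalization, centring on the median, normexp background correction (offset 50), the series matrix, no filter on dim probes, only probes well above background on all arrays, and spots marked by the scanner software kept. Others were slide as a random block (statmod 1.5.0), the mean of each slide's 2 arrays, position on the slide, replicate number as a block, only the groups compared, 1 probe per gene, trend and robust eBayes, a 2-fold threshold, and each array left out in turn. In all there were 43 settings, 4 of them chosen after the data were seen.

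The pipeline was tested on simulated data made from the 6 h comparison. With 50 probes planted at each of 4 effects, 38% were recovered at a log2 change of 1, 72% at 2, 92% at 3 and 92% at 4, and 13 of 27015 unplanted probes were called. A planted list of 50 probes moved by -0.5 was found (adjusted p = 1.4e-14), and an unmoved one was not (0.95). A search for probes that split the arrays found 39 of 40 planted ones. The simulated noise was independent between probes and arrays, with no correlation within slides or between genes. These rates therefore need not hold for the real data. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.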

Results

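Between 21.1% (mock 24 h replicate 4) and 35.8% (Xcc 6 h replicate 2) of the 91854 probes lay well above background on an array, and 27265 probes were tested. Of the tested probes, 52.6% were well above background on mock 24 h replicate 4 and 77.2% on replicate 3 of the same slide, against 75.7% to 98.4% on the other arrays. Correlations across probes, which are not independent of each other, ran from 0.848 to 0.977 within groups and from 0.768 to 0.986 between groups. The first 2 principal components held 27.5% and 22.1% of the variance.

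On 6 arrays, 131 probes lay at least 3 log2 units below their level on each of the other 18 arrays, a set chosen after the data were seen. Their median level was -8.13 on mock 6 h replicate 1, -8.06 on Xcc 24 h replicate 4, -7.92, -8.52 and -7.94 on mock 48 h replicates 1 to 3, and -7.12 on Xcc 48 h replicate 4. On the other arrays it lay between -2.14 and -1.56. Of these probes 71 carry a name, and 0 were among the probes called at 6 or 48 h. The gap by which they were picked spreads them widely within the mock 6 h, mock 48 h and Xcc 48 h groups. A call was therefore unlikely from the start, and the 0 does not show that the calls are free of this pattern.

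**Figure D1:**
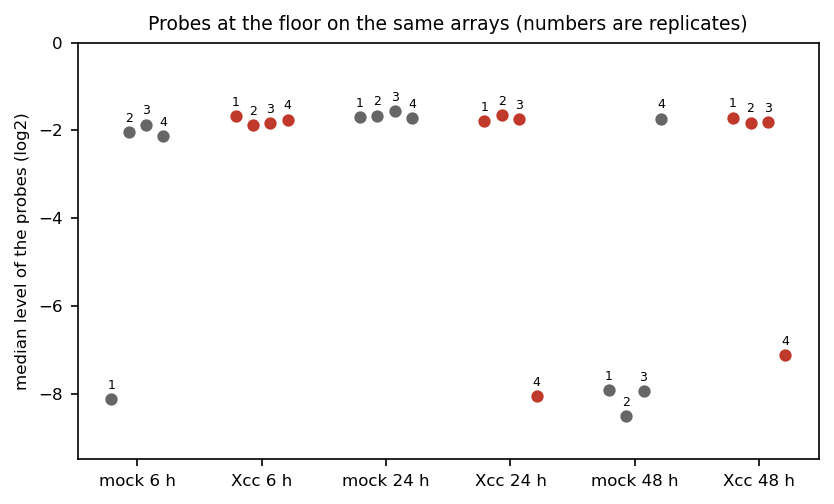
Median level (normalized log2 signal) of the 131 probes on each of the 24 arrays, by group and with replicate numbers beside the points. The 6 arrays at the bottom are those named in the text.

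At 6 h, enzymes of flavonoid and anthocyanin synthesis were higher in Xcc-inoculated leaves. Chalcone synthase, the first enzyme of the pathway, rose from -4.05 ± 1.1 in mock to 1.47 ± 0.83 with Xcc (mean ± SD, n = 4 and 4), a log2 change of 5.52 (SE 1.09, adjusted p = 0.029). Chalcone synthase 3 rose by 6.23 (SE 1.29, adjusted p = 0.0323), with 1 of 4 mock arrays well above background. Dihydroflavonol 4-reductase was higher by at least 59.3-fold (adjusted p = 0.032) and anthocyanin 5-O-glucosyltransferase by at least 27.6-fold (0.0413), each with 0 mock arrays well above background. The flavonoid list had 6 of its 50 probes up and 0 down, or 16 up and 2 down adjusted over the list alone, with a median log2 change of 0.23 (camera adjusted p = 0.013). It had an adjusted p = 0.55 with an estimated correlation. Flavonol-3-O-glycoside-7-O-glucosyltransferase 1 rose by 0.98 (SE 0.21, adjusted p = 0.0381).

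Among the largest rises at 6 h were probes that, by their names on the array, may belong to the chain elongation that feeds methionine-derived glucosinolates. Methylthioalkylmalate synthase rose by 5.74 (SE 1.28, adjusted p = 0.043), branched-chain amino acid aminotransferase 4 by 5.71 (SE 0.95, 0.0138) and 2-isopropylmalate synthase by 5.62 (SE 1.00, 0.0205). They were well above background on 1, 2 and 3 of 4 mock arrays. The name 2-isopropylmalate synthase does not by itself place a gene in this pathway, and a probe of like name (B_1070807) was at -0.44. A protein of the locus At5g14200 rose by 4.89 (SE 1.02, adjusted p = 0.0336; 2 mock arrays well above background). The keyword list of aliphatic glucosinolates had 1 of 29 probes up and 0 down, and 1 up adjusted over the list alone. Its median of -0.20, its mean of 0.07 and its test (down, adjusted p = 0.78) differ in sign. UDP-glucose:sinapate glucosyltransferase rose by 5.64 (SE 0.98, adjusted p = 0.0175; 1 mock array), and a glutathione S-transferase-like protein by at least 18.6-fold (0.0413; 0 mock arrays).

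Ethylene-responsive transcription factor 4 rose by 2.82 at 6 h (SE 0.57, adjusted p = 0.0318). It was the 1 probe called of 126 in the ethylene list, against 13 up and 1 down adjusted over the list alone. The list as a whole was up (median 0.25, adjusted p = 0.013), with an adjusted p = 0.55 with an estimated correlation, and it was lost without the 6 arrays that stand apart (0.15), without mock replicate 1 and without Xcc replicate 4. A ClpB-like heat shock protein rose by 1.57 (SE 0.30, adjusted p = 0.0274).

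Photosynthesis transcripts were lower at 6 h. Rubisco activase fell by 1.09 (SE 0.24, adjusted p = 0.0392), the 33 kDa oxygen-evolving protein of photosystem II fell by 1.24 (SE 0.28, 0.043) and oxygen-evolving enhancer protein 2-1 fell by 1.11 (SE 0.25, 0.043). In the photosynthesis list 93 of 108 probes were lower, 3 of them called and 19 adjusted over the list alone (median -0.35, adjusted p = 2.5e-08). The chlorophyll synthesis list of 25 probes was also down (median -0.54, adjusted p = 0.0086), with 0 probes called and 1 lower adjusted over the list alone. Both lists had an adjusted p = 0.55 with an estimated correlation, and chlorophyll synthesis was lost with 1 probe per gene (0.19).

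The largest fall at 6 h was that of a cold acclimation protein homolog, which fell by 3.37 (SE 0.69, adjusted p = 0.032; 3 of 4 Xcc arrays well above background). A Feebly-like protein fell by 2.53 (SE 0.57, adjusted p = 0.043; 2 Xcc arrays) and an alpha-mannosidase fell by 2.29 (SE 0.41, 0.0205; 1 Xcc array). Loci At1g25230 and At1g02640 were lower by at least 3.94-fold (adjusted p = 0.0413) and at least 4.06-fold (0.032), and a cytochrome P450-like protein by at least 3.59-fold (0.0223), with 0 Xcc arrays well above background. The F-box/Kelch protein At5g03000 fell by 2.08 (adjusted p = 0.043; 2 Xcc arrays) and a putative isocitrate dehydrogenase fell by 1.81 (0.032; 1 Xcc array). A putative phytochrome fell by 1.80 (adjusted p = 0.049) and the locus At3g62770 fell by 1.78 (0.047), each with 2 Xcc arrays well above background.

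Smaller falls at 6 h included 2 peroxidases and 2 genes of the actin family. L-ascorbate peroxidase 4 fell by 1.52 (SE 0.31, adjusted p = 0.032), peroxidase 12 fell by 1.27 (SE 0.28, 0.0392) and sugar transporter ERD6-like 6 fell by 1.00 (SE 0.21, 0.037). Actin-2 fell by 1.25 (SE 0.27, adjusted p = 0.0367), and 2 probes of actin-related protein 8 fell by 1.46 (0.0436) and fell by 1.06 (0.0477). They were the 3 called of 90 in the housekeeping list, with 11 lower adjusted over the list alone (median -0.11, adjusted p = 0.075).

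In all, limma called 127 probes up and 70 down at 6 h, and 5381 had an unadjusted p under 0.05 where 1363 are expected by chance. Of the 197 calls, 117 carry a name, 19 are in a list, 172 changed at least 2-fold, and 177 have values that do not overlap between the groups, as 13.2% of all tested probes do (2.86% by chance). Quantile normalization left 38 up and 10 down, normexp 26 and 25, the 75th percentile over all probes 88 and 17, and slide as a random block 5 in all, while centring on the median gave 137 and 118. Of the 32 called genes named at 6 h, quantile normalization and normexp kept 8 each, the 75th percentile over all probes 18, no filter 1, and slide as a random block and slide means 0, with directions unchanged. The count was 1327 without mock replicate 1, 3 without mock replicate 2, 4 without mock replicate 4, and 40, 3 and 93 without Xcc replicates 2, 3 and 4.

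**Figure D2:**
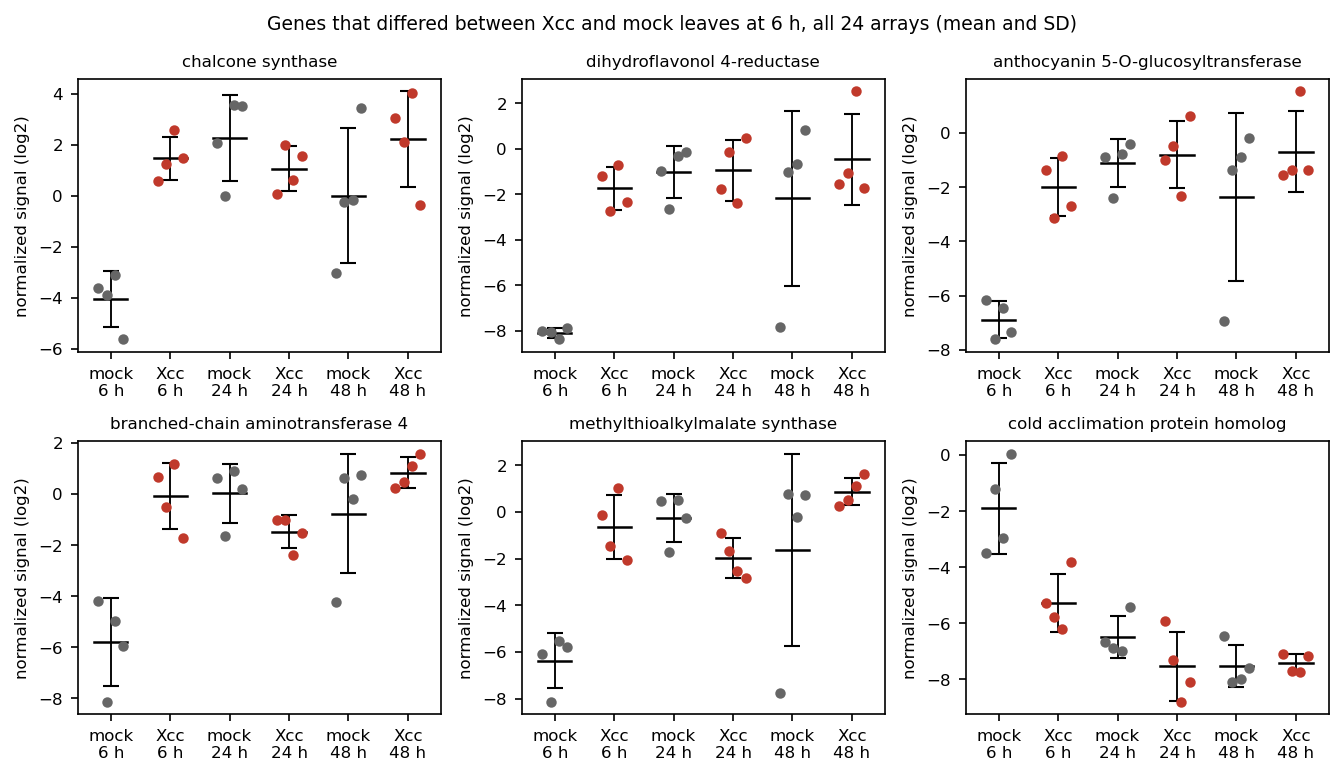
Normalized log2 signal of 6 genes called at 6 h on all 24 arrays, by group (mock or Xcc, at 6, 24 and 48 h). Points are arrays and bars are the mean and SD of 4 arrays.

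Many transcripts higher with Xcc at 6 h were also higher in mock leaves at 24 h than at 6 h. In mock leaves from 6 to 24 h, chalcone synthase 3 rose by 7.26 (SE 1.29, adjusted p = 0.000478) and UDP-glucose:sinapate glucosyltransferase rose by 8.44 (SE 0.98, 8.43e-06). Of the 197 probes called at 6 h, 182 moved in the same direction in mock leaves from 6 to 24 h, 138 of them called there too. For 78 of the 127 rises and 16 of the 70 falls, the Xcc 6 h mean lies between the mock means at 6 and 24 h. The 2 comparisons share the mock 6 h arrays, which by itself gives part of such a match. Across probes the 2 changes correlated at 0.57, against a mean of 0.21 in simulated data with shared arrays and no effect. With the 4 mock 6 h arrays divided between the comparisons in each of 6 ways, the correlation was 0.3 to 0.45. Of the 200 strongest probes 55.5% to 88% then moved in the same direction, against 55.5% to 66.2% of all probes.

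At 24 h, genes tied to pattern-triggered immunity lay higher with Xcc as a list. Its 5 probes of *WRKY33* (Probable WRKY transcription factor 33) were higher by 1.51 to 2.05, with 1.90 for B_1074852 (SE 0.72, adjusted p = 0.687, n = 4 and 4). The list has 11 probes, 8 of them higher, with a median of 0.81 and an adjusted p = 0.00054, and an adjusted p = 0.73 with an estimated correlation. It was lost without the slide of mock 24 h replicates 3 and 4 (adjusted p = 0.10), with no filter on dim probes (0.36; median -1.07), with 1 probe per gene (0.48), and among probes well above background on all arrays (0.87).

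Photosynthesis and flavonoid transcripts lay lower as lists at 24 h. In photosynthesis 99 of 108 probes were lower (median -0.32, adjusted p = 1.2e-08), and its strongest member, the Rubisco small chain 1A, was at -1.03 (SE 0.33, adjusted p = 0.687). In the flavonoid list 36 of 50 were lower (median -0.29, adjusted p = 0.011), with chalcone-flavonone isomerase at -1.21 (SE 0.34, adjusted p = 0.687). Both lists had an adjusted p = 0.73 with an estimated correlation. The 75th percentile over all probes turned the medians of photosynthesis and flavonoids to 0.22 and 0.25, against 0.49 for all probes, and the test still gave both as down. Under normexp they were lost (adjusted p = 0.61 and 0.25), as with no filter (0.82 and 0.42). The flavonoid list was also lost with 1 probe per gene (0.092), without the slide of mock 24 h replicates 3 and 4 (0.48), and with mock replicate 4, Xcc replicate 1 or Xcc replicate 3 left out.

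No single gene was called at 24 h: limma gave 0 probes past the threshold, with 1933 at an unadjusted p under 0.05 and a smallest adjusted p of 0.687. The 5 named probes with the smallest p and lower values were a putative disease resistance protein (-2.03, SE 0.46), a salt-induced AAA-type ATPase (-1.20), a protein similar to embryo-specific protein 3 (-2.64), a steroid 5alpha-reductase-like protein (-0.73) and a protein phosphatase 2A B'' subunit (-1.18). The 5 with higher values were an RRM-containing protein (1.12, SE 0.30), a protein with ubiquitin interaction and LIM domains (0.85), an amino acid permease-like protein (0.64), the G protein alpha-1 subunit (0.77) and At5g18610 (0.53). All had an adjusted p of 0.687.

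At 48 h, 8 of 37 probes of chloroplast-encoded genes were called lower with Xcc and 0 higher. The set was chosen after the results were seen. Of the 37 probes 25 were lower and 12 higher, among the latter the ATP synthase epsilon chain (0.31) and a second ycf3 probe (B_1064354, 0.59). As the labelling starts from poly(A) tails, another way of labelling would be needed to test these falls. ATP synthase subunit beta (B_1061314) fell from 4.99 ± 0.57 in mock to 2.65 ± 0.77 with Xcc (n = 4 and 4), a log2 change of -2.34 (SE 0.37, adjusted p = 0.0231). The 47 kDa protein of photosystem II fell by 1.59 (SE 0.33, adjusted p = 0.0427), a chloroplast envelope membrane protein fell by 1.60 (SE 0.30, 0.0342) and the photosystem I assembly protein ycf3 (X_1082049) fell by 1.03 (SE 0.23, 0.0486). The 49 kDa NADH dehydrogenase protein fell by 2.56 (SE 0.52, adjusted p = 0.0422; 3 Xcc arrays well above background), and a second ATP synthase beta probe was lower by at least 5.21-fold (0.025; 0 Xcc arrays). The photosynthesis list was down, with 79 of 108 probes lower, 1 called and 3 adjusted over the list alone (median -0.25, adjusted p = 0.0015, and adjusted p = 0.75 with an estimated correlation). It was lost under quantile normalization (adjusted p = 0.40), with the series matrix (0.35), and without the 6 arrays that stand apart, which leaves 1 mock array.

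Other transcripts lower at 48 h include At1g70700, by at least 7.21-fold (adjusted p = 0.0231), a 14-3-3-like protein by at least 3.50-fold (0.0486) and mitochondrial aspartate aminotransferase by at least 3.16-fold (0.0231). In Arabidopsis At1g70700 is the locus of *JAZ9*, a jasmonate response gene. The phytochrome A-associated F-box protein was lower by at least 3.05-fold (adjusted p = 0.0378) and At1g52780 by at least 2.98-fold (0.0427). All 5 had 0 Xcc arrays well above background. Normexp raised the median of all probes to 0.42 at 48 h; these 5 and the second ATP synthase beta probe then had changes of 0.04 to 0.54, 5 of the 6 still below that median and none called. A heat shock factor, hsf8, fell by 1.05 (SE 0.22, adjusted p = 0.0427).

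Transcripts higher at 48 h include a cell-wall enzyme and several regulators. Xyloglucan endotransglucosylase/hydrolase 23 was higher by at least 5.67-fold (adjusted p = 0.0427), with 0 mock and 2 Xcc arrays well above background. Cytokinin response factor 3 rose by 2.11 (SE 0.36, adjusted p = 0.025; 1 mock and 3 Xcc arrays), heat stress transcription factor C-1 by 1.85 (SE 0.35, 0.0342) and a calcium-dependent protein kinase by 1.66 (SE 0.34, 0.0427). Chloroplast glucose-6-phosphate dehydrogenase 3 rose from -0.71 ± 0.46 to 1.28 ± 1.1, by 1.99 (SE 0.38, adjusted p = 0.0342), and Cax51 rose by 2.02 (SE 0.44, 0.0486). Of loci without a fuller name, At5g42146 rose by 2.38 (SE 0.53, adjusted p = 0.0495; 1 mock array) and At3g22390 by 1.64 (SE 0.28, 0.025). At5g41100 rose by at least 4.44-fold (adjusted p = 0.0378; 0 mock and 3 Xcc arrays), and RFL1 by at least 3.36-fold (0.0429; 0 mock and 2 Xcc arrays).

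Lists of water stress, phloem and surface genes were higher at 48 h. Dehydrin rose by 1.71 (SE 0.38, adjusted p = 0.0486) and was the 1 call of 45 in the abscisic acid and dehydration list, with 4 up adjusted over the list alone and 34 higher (median 0.27, adjusted p = 0.038). The 3 phloem probes were all higher (median 1.19, adjusted p = 0.019; 0 called, 2 adjusted over the list alone), with phloem protein 2-like A1 at 1.38 (adjusted p = 0.0837). Of 31 epidermis and guard cell probes 22 were higher (median 0.60, adjusted p = 0.014; 0 called, 1 adjusted over the list alone), with 3-ketoacyl-CoA synthase 16 at 2.09 (adjusted p = 0.0601; 1 mock array well above background). These lists had adjusted p = 0.63, 0.51 and 0.75 with an estimated correlation. Under normexp all 3 were lost (adjusted p = 0.22, 0.068 and 0.073), as they were with no filter (0.15, 0.10 and 0.15) and on probes well above background on all arrays (0.38, 0.051 and 0.38). With 1 probe per gene the first 2 were lost (0.10 and 0.14). Leaving out mock replicate 3 or 4 lost both of these, leaving out Xcc replicate 3 or 4 lost abscisic acid, and leaving out mock replicate 1 lost epidermis. Leaving out the 6 arrays that stand apart leaves 1 mock array and tests nothing here. With a term for those 6 the medians were 0.24, 1.1 and 0.44 (adjusted p = 0.032, 0.014 and 0.012). With the 75th percentile over all probes the median of the abscisic acid list was -0.13 against -0.40 for all probes, and the test still gave it as up.

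Ethylene-responsive factors supplied 2 calls of 126 at 48 h, cytokinin response factor 3 and *ERF058*, which rose by 1.49 (SE 0.33, adjusted p = 0.0495). Adjusted over the list alone, 2 were up and 1 down, and the ethylene list was not past its threshold (median 0.12, adjusted p = 0.49).

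In all, limma called 51 probes up and 79 down at 48 h, with 5057 at an unadjusted p under 0.05. Of the 130 calls, 85 carry a name, 5 are in a list, 112 changed at least 2-fold, and 111 have values that do not overlap between groups, as 6.68% of all tested probes do. Quantile normalization left 0 up and 4 down, normexp 0 and 1, the 75th percentile over all probes 0 and 3, and slide as a random block 0 (3574 at an unadjusted p under 0.05), while centring on the median gave 64 and 170. The 6 arrays that stand apart include 3 mock and 1 Xcc array here: 10 probes were called with a term for them (8 in both), which keeps 3 of the 24 called genes named. With the term the 24 changes ran from 0.94 to 3.42 in size. Quantile normalization and normexp kept 1 each of the 24, the 75th percentile over all probes 2, and no filter, slide as a random block, slide means and only the groups compared 0. In the last 3 of these settings the sizes stayed at 1.03 to 3.11. Leaving out the 6 arrays is no test here, since mock 48 h would then be replicate 4 alone. The count was 1, 0, 0 and 3759 without mock replicates 1, 2, 3 and 4, and 36, 5 and 43 without Xcc replicates 1, 3 and 4.

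**Figure D3:**
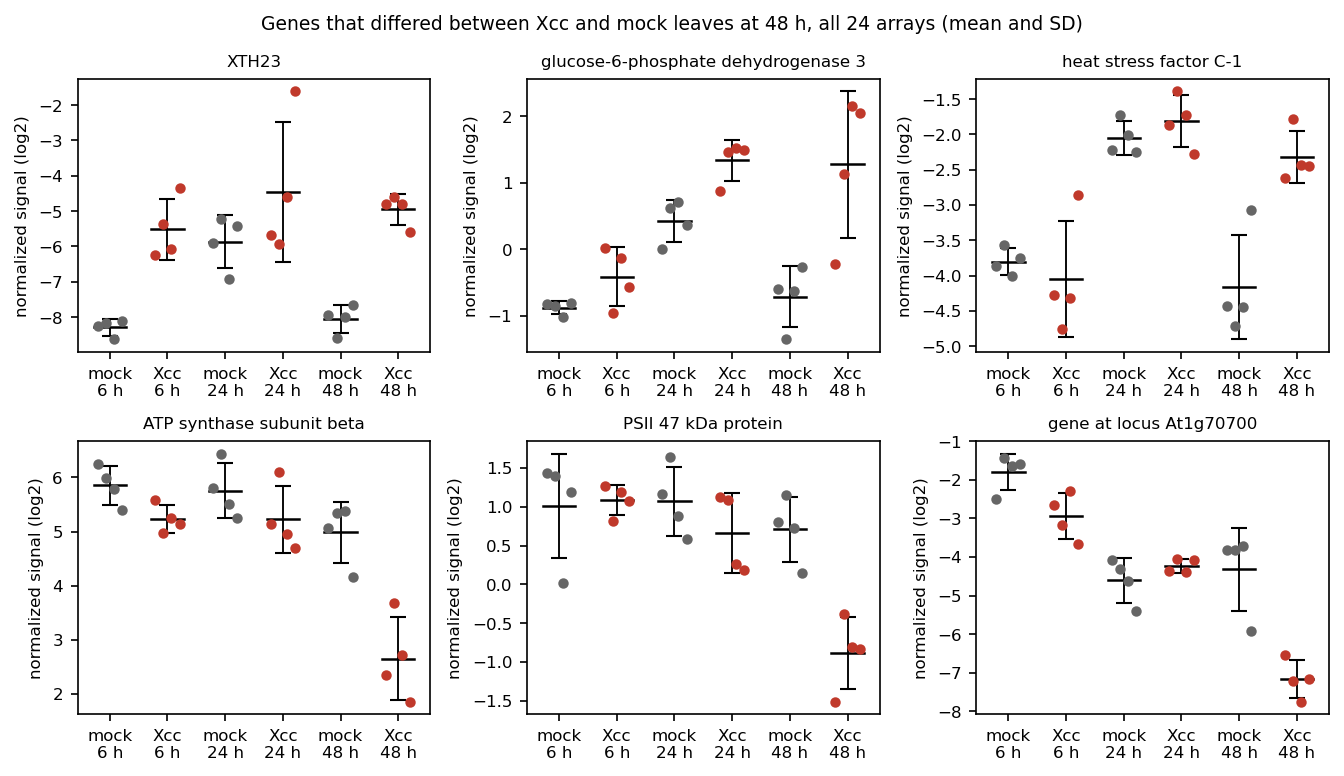
Normalized log2 signal of 6 genes called at 48 h on all 24 arrays, by group (mock or Xcc, at 6, 24 and 48 h). Points are arrays and bars are the mean and SD of 4 arrays. Under normexp At1g70700 was at 0.17, against 0.42 for all probes.

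Called at both 6 and 48 h were 3 probes, all in the same direction, where 0.44 are expected by chance. Xyloglucan endotransglucosylase/hydrolase 23 was higher by at least 4.42-fold at 6 h (adjusted p = 0.0495; 0 mock and 3 Xcc arrays well above background) and at least 5.67-fold at 48 h (0.0427). A probe of the locus At5g13630, a magnesium chelatase subunit in Arabidopsis, fell by 1.11 (SE 0.22, adjusted p = 0.0318) and fell by 1.06 (SE 0.22, 0.0427). The third, B_1010109, has no gene name and fell by 0.78 (adjusted p = 0.0498) and fell by 0.81 (0.0495; 2 of 4 Xcc arrays at 48 h). These genes were picked because they were called at both times, after their values were seen. Quantile normalization, normexp and slide as a random block each left 0 shared probes. Leaving out mock 48 h replicate 4 gave 250, while leaving out most of the other arrays of these times gave 0.

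Effects of Xcc differed between times for 3 lists. Flavonoid probes lay lower in the 24 h effect than in the 6 h effect (median difference -0.41, mean -1.34, 0 up and 16 down adjusted over the list alone, adjusted p = 8.5e-05, and adjusted p = 0.31 with an estimated correlation). From 24 to 48 h the phloem list moved up (median difference 1.22, 3 up adjusted over the list alone, adjusted p = 0.048), as did epidermis and guard cells (0.62, adjusted p = 0.048). With an estimated correlation their adjusted p = 0.67 and 0.90. For single probes limma gave 0 past the threshold in each of the 3 differences, with 2864 (24 h less 6 h), 3065 (48 h less 24 h) and 2748 (48 h less 6 h) at an unadjusted p under 0.05. Leaving out each array in turn gave 0 to 11, 0 to 446 and 0 to 9 in that order. The 446 and the 9 were without mock 48 h replicate 4.

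Defence marker genes fixed in advance, each judged by its tested probe with the highest mean level, did not pass the test at any time. Tested were 3 probes of *PR1*, 4 of *WRKY70*, 3 of *LOX2*, 2 of *ICS1* and 6 of the MtN3 kind. Changes with Xcc of the other probes are not given here, among them the *PR1* probe B_1079885 named below for mock leaves. *PR1* (B_1087585) was at 0.15, 0.42 and -0.17 at 6, 24 and 48 h (adjusted p = 0.877, 0.793 and 0.864), and *PR5* (B_1064071) at 0.22, -0.23 and 0.54 (0.846, 0.911 and 0.587). *ICS1*, which makes the precursor of salicylic acid, was at -0.13, 0.11 and -0.08 (adjusted p = 0.881, 0.948 and 0.926), and *WRKY70* at 0.15, -0.26 and -0.72 (0.932, 0.932 and 0.595). *NCED3* of abscisic acid synthesis was at 0.53, 0.26 and 0.18 (adjusted p = 0.438, 0.855 and 0.83), and a homolog of the MtN3 sugar transporters at -0.47, 0.21 and 0.12 (0.373, 0.846 and 0.853). *LOX2* was at -0.21, 0.21 and -0.69 (adjusted p = 0.852, 0.925 and 0.478), but its probe was saturated on 3, 2 and 3 mock arrays and 1, 4 and 0 Xcc arrays. The patterns used for *PR2*, *PDF1.2*, *PAD3*, *CYP79B2*, *FRK1*, *JAZ10*, *SAG12* and *SAG13* matched no probe, and the 1 *VSP2* probe was too dim to test. Beta-1,3-glucanases, the family of *PR2*, are on the array under other names, some of them in the list of pathogenesis-related proteins.

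Hormone and defence lists that were not past the threshold at any time had the following medians at 6, 24 and 48 h. Salicylic acid signalling (14 probes) was at 0.09, -0.39 and -0.24 (adjusted p = 0.58, 0.18 and 0.39), and its 1 probe up adjusted over the list alone was *WRKY18*, higher by at least 3.31-fold at 6 h (adjusted p = 0.0641; 0 mock arrays well above background). Pathogenesis-related proteins (53) were at 0.08, -0.14 and 0.27 (adjusted p = 0.58, 0.59 and 0.39), and their means of 0.00 at 24 h and -0.04 at 48 h, like the test (up), do not follow the medians. Jasmonate (33) was at 0.09, 0.05 and -0.17 (adjusted p = 0.51, 0.62 and 0.42), with a mean of -0.05 at 24 h, and *COI1* was at 1.1 at 48 h (adjusted p = 0.106). Its keywords do not match the At1g70700 probe, the locus of *JAZ9* in Arabidopsis, which was called lower at 48 h but not under normexp. Indole glucosinolates (2 probes of *CYP83B1*) were at 0.42, 0.54 and -1.52 (adjusted p = 0.58, 0.56 and 0.098), both lower at 48 h adjusted over the list alone. Aliphatic glucosinolates were at -0.07 at 24 h (mean 0.16, test up, adjusted p = 0.57) and -0.44 at 48 h (0.098). Phenylpropanoids and lignin (28) were at 0.18, -0.15 and 0.17 (adjusted p = 0.28, 0.98 and 0.58), with a mean of 0.06 and a test up at 24 h, and phenylalanine ammonia-lyase at 1.38 at 6 h (adjusted p = 0.0834). Auxin response (121) was at 0.01, -0.02 (test up) and 0.11 (adjusted p = 0.58, 0.72 and 0.39; 1 up and 1 down at 48 h adjusted over the list alone).

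Stress and cell lists gave no call as lists either. Oxidative stress (113 probes) was at 0.03, -0.12 and -0.15 (adjusted p = 0.57, 0.59 and 0.12), with 1 up and 2 down called at 6 h and 0 at 48 h. Adjusted over the list alone its counts were 2 up and 2 down, then 2 up and 3 down. Heat shock (81) was at 0.05, -0.02 and -0.01 (adjusted p = 0.28, 0.61 and 0.47; means 0.02 and 0.01 at 24 and 48 h), with 1 up at 6 h and 1 down at 48 h, or 5 up and 1 down, then 1 down, adjusted over the list alone. Folding in the endoplasmic reticulum (29) was at 0.17, 0.02 and -0.04 (adjusted p = 0.28, 0.69 and 0.50; mean -0.07 at 24 h, 1 down at 48 h adjusted over the list alone). Wounding, touch and cold (2) was at 1.17, 0.29 and 0.76 (adjusted p = 0.089, 0.59 and 0.37; 1 up at 6 h adjusted over the list alone), and senescence (18) at -0.35, -0.05 and 0.32 (0.13, 0.80 and 0.42).

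Sugar transport (37) was at -0.23, 0.04 and -0.15 (adjusted p = 0.13, 0.55 and 0.39), with 1 down at 6 h, or 2 adjusted over the list alone. The circadian clock (13) was at 0.21, -0.38 and 0.28 (adjusted p = 0.37, 0.90 and 0.74; mean 0.01 and test up at 24 h), xylem (7) at -0.29, 0.40 and 0.19 (0.64, 0.48 and 0.51) and cell division (39) at -0.05, -0.12 and -0.24 (0.67, 0.59 and 0.30). Housekeeping was at -0.07 at 24 h (test up, adjusted p = 0.90) and -0.10 at 48 h (0.12). Of the lists called at other times, abscisic acid had 6 up adjusted over the list alone at 6 h (median 0.20, adjusted p = 0.055) and was at -0.07 at 24 h (mean 0.04, 0.21). Epidermis was at 0.26 at 6 h (4 up adjusted over the list alone, adjusted p = 0.075) and -0.15 at 24 h (0.76), and phloem at 0.75 and -0.03 (0.38 and 0.76). Chlorophyll synthesis was at -0.20 and -0.18 at 24 and 48 h (adjusted p = 0.20 and 0.098; 4 down at 48 h adjusted over the list alone). Pattern-triggered immunity was at -0.03 at 6 h (mean 0.28, adjusted p = 0.58) and 0.58 at 48 h (0.39), ethylene at 0.02 at 24 h (mean -0.03, 0.76) and flavonoids at 0.08 at 48 h (0.55). At 24 h each of the 25 lists had 0 calls, also adjusted over the list alone.

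**Figure D4:**
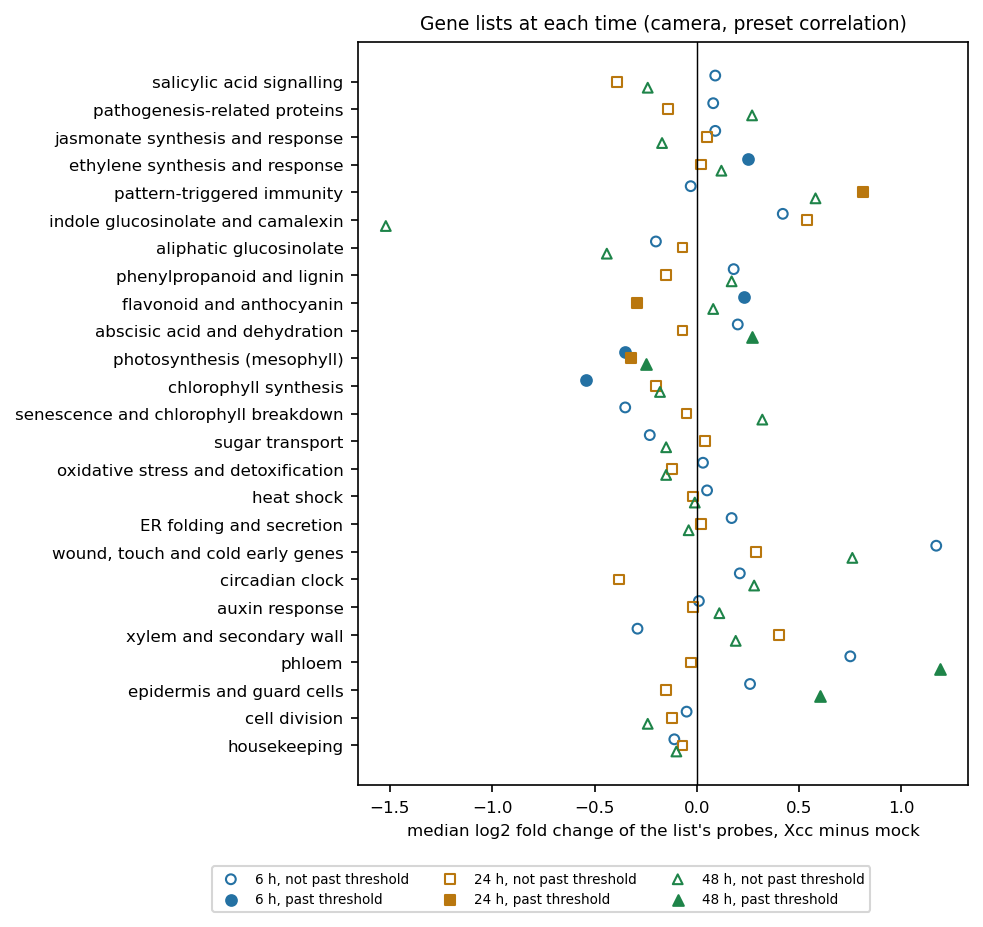
Median log2 change (Xcc less mock) of the probes in each gene list at 6, 24 and 48 h; filled symbols are lists past the threshold with the preset correlation, and none is with an estimated one. Under the 75th percentile over all probes the 24 h medians of photosynthesis and flavonoids and the 48 h median of abscisic acid have the other sign, with all probes at 0.49 and -0.40.

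The scaling shifts all probes together between groups. In Xcc against mock the median of all tested probes was -0.02, -0.05 and 0.01 at 6, 24 and 48 h. It was 0.06, 0.49 and -0.40 with the 75th percentile over all probes, -0.02, 0.29 and -0.21 under quantile normalization, and -0.13, -0.31 and 0.42 under normexp.

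More probes were called between mock leaves at 6 and 24 h than with Xcc at any time. The genes named for mock leaves were chosen after their values were seen. Each slide held arrays of 1 group, and the 6 h slides carry a separate run of slide numbers from the 24 and 48 h slides. In the mock comparisons time thus cannot be told apart from slide, as treatment cannot in the Xcc comparisons. Time also goes with the humidity setting and possibly with the time of day. From 6 to 24 h a calmodulin rose by 8.20 (SE 0.83, adjusted p = 2.17e-06; 1 array at 6 h well above background) and L-asparaginase 2 by 8.07 (SE 1.06, 2.87e-05; 1 array). Germin-like protein 3-3 fell by 6.95 (SE 1.21, adjusted p = 0.000377) and germin-like protein 1 fell by 5.51 (SE 0.95, 0.000343). The clock genes Adagio protein 2 and *APRR1* fell by 6.17 (SE 1.25, adjusted p = 0.00143) and fell by 5.90 (SE 0.90, 0.000113), each with 1 array at 24 h well above background. The circadian list had 6 probes up and 6 down of 13, or 6 and 7 adjusted over the list alone, and its median of -1.89 and mean of 0.52 differ in sign (adjusted p = 0.79).

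Lists past the threshold in mock leaves from 6 to 24 h were salicylic acid signalling (up, median 1.27, 4 up and 0 down, 5 and 0 adjusted over the list alone, adjusted p = 0.022), ethylene (up, 0.50, 39 and 6, 42 and 8 adjusted over the list alone, 0.0094) and phloem (up, 2.36, 3 and 0, 3 and 0 adjusted over the list alone, 0.0094). Lower were aliphatic glucosinolates (median -0.79, 1 up and 6 down, 2 and 9 adjusted over the list alone, adjusted p = 0.043), folding in the endoplasmic reticulum (-0.44, 0 and 3, 0 and 0 adjusted over the list alone, 0.03) and housekeeping (-0.17, 6 and 19, 6 and 20 adjusted over the list alone, 0.0094). With an estimated correlation the adjusted p = 0.42, 0.57, 0.33, 0.73, 0.73 and 0.42 in that order. Under normexp the medians of aliphatic glucosinolates, endoplasmic reticulum folding and housekeeping were 0.03, 0.15 and 0.19, and with the 75th percentile over all probes that of ethylene was -0.09, while the test kept its direction each time. Aliphatic glucosinolates and endoplasmic reticulum folding were lost under quantile normalization (adjusted p = 0.37 and 0.097) and with the 75th percentile over all probes (0.33 and 0.12). Centring on the median lost aliphatic glucosinolates (0.074), and normexp salicylic acid signalling (0.072). Without the 6 arrays that stand apart ethylene (0.053) and folding (0.32) were lost, and with a term for them aliphatic glucosinolates (0.10) and folding (0.092).

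From 24 to 48 h in mock leaves, 2 lipid-transfer proteins fell and several pathogenesis-related proteins rose. Among the latter, protein R major form was called up (adjusted p = 0.0394), with 0 arrays at 24 h well above background. Pathogenesis-related protein 1 (B_1079885) rose by 5.49 (SE 1.68, adjusted p = 0.0468; 2 arrays at 24 h well above background) and 2 probes of beta-1,3-glucanase by 5.15 (SE 1.14, 0.0153) and 5.30 (SE 1.21, 0.017). A nonspecific lipid-transfer protein fell by 5.40 (SE 1.38, adjusted p = 0.0268; 2 arrays at 48 h) and nonspecific lipid-transfer protein 6 fell by 5.09 (SE 1.02, 0.0112; 1 array). Of the mock 48 h arrays 3 of 4, and of the mock 24 h arrays 0, are among the 6 that stand apart. With a term for those 6 none of the named genes was called, *PR1* being at 2.26 (adjusted p = 0.482) and the lipid-transfer proteins at -2.67 (0.308) and -3.94 (0.143). The list of pathogenesis-related proteins had 4 up and 3 down, or 5 and 4 adjusted over the list alone (median -0.38, mean 0.11, adjusted p = 0.99). As lists, epidermis and guard cells (median -1.60, 0 up and 15 down, 0 and 18 adjusted over the list alone, adjusted p = 2.9e-07), ethylene (-0.51, 1 and 24, 4 and 40 adjusted over the list alone, 0.00065) and flavonoids (-0.66, 0 and 8, 0 and 8 adjusted over the list alone, 0.034) were down, and folding in the endoplasmic reticulum was up (0.54, 3 and 0, 4 and 0 adjusted over the list alone, 0.00065). With an estimated correlation the adjusted p = 0.41, 0.70, 0.80 and 0.80. With the 75th percentile over all probes the medians of ethylene and flavonoids were 0.22 and 0.07, the test still giving both as down, and under normexp flavonoids were lost (adjusted p = 0.11). With a term for the 6 arrays epidermis was at -1.22 (adjusted p = 5.5e-09), ethylene at -0.50 (1.5e-05) and flavonoids at -0.48 (0.0013), and folding in the endoplasmic reticulum was lost (0.44).

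In mock leaves limma called 3165 probes up and 2405 down from 6 to 24 h (3853 at least 2-fold), and 716 up and 1664 down from 24 to 48 h (1712 at least 2-fold). With a term for the 6 arrays that stand apart the 24 to 48 h count was 12. The split turns with the scaling: 1992 and 4875, then 2510 and 494 under quantile normalization; 5872 and 1239, then 17 and 110 under normexp; 1266 and 5870, then 7094 and 498 with the 75th percentile over all probes. The median of all probes moved with it, from 0.05 and -0.10 to -0.35 and 0.31, 0.46 and -0.18, and -0.53 and 0.63. From 24 to 48 h, leaving out mock 24 h replicates 1, 2, 3 and 4 gave 923, 1252, 823 and 1019 probes, and leaving out mock 48 h replicates 1 to 4 gave 483, 1295, 665 and 4948. Without the slide of mock 24 h replicates 3 and 4 the counts were 2496 from 6 to 24 h and 43 from 24 to 48 h.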

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

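All tests in this part of other alleles, exchanged labels, the time course and weak signal were chosen after the results they bear on were seen.

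Groups were searched for a single replicate far from its 3 fellows by Dixon's ratio. By chance about 1 in 20 groups is picked, and 22 of 300 gene groups were (7.33%), with 11 of 60 for array measures.

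Among array measures, mock 48 h replicate 2 had 30.9% of probes well above background (the others 26.1, 26.8 and 26.8), and mock 6 h replicate 2 had 80 spots marked by the scanner software (1, 3 and 3). Xcc 6 h replicate 2 had a median processed signal of 4.41 (3.25, 3.32 and 3.33), and Xcc 24 h replicate 3 a median background of 24.5 (25 on each of the others). On the first principal component mock 6 h replicate 3 lay at -97.4 (-121, -121 and -117). On the second, mock 6 h replicate 1 lay at 58.2 (-50.5, -44.2 and -32.9) and mock 48 h replicate 4 at -13 (110, 111 and 126). The median of the 131 probes described in the report was apart from its group on mock 6 h replicate 1 (-8.13), Xcc 24 h replicate 4 (-8.06), mock 48 h replicate 4 (-1.74) and Xcc 48 h replicate 4 (-7.12).

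Genes with a single replicate apart at 6 h were alpha-mannosidase on Xcc replicate 4 (-5.41), the cytochrome P450-like protein on mock replicate 1 (-5.95) and phenylalanine ammonia-lyase on mock replicate 1 (-4.42). *CYP83B1* was apart on replicate 4 of both Xcc (0.55) and mock (-0.44), and *PR5* on mock replicate 4 (-5.95). At 24 h the salt-induced ATPase (-4.34) and the phosphatase 2A subunit (-3.45) were apart on mock replicate 4, and cinnamoyl-CoA reductase on mock replicate 2 (-4.16). Heat shock protein 81-2 was apart on mock replicate 1 (-2.81) and calreticulin on Xcc replicate 4 (-8.10).

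At 48 h, 6 gene groups had mock replicate 4 apart: heat stress transcription factor C-1 (-3.07), At1g70700 (-5.93), the 49 kDa NADH dehydrogenase protein (-3.40), *COI1* (-3.82), a myrosinase-binding protein (-1.52) and monodehydroascorbate reductase (-6.41). The NADH dehydrogenase protein (-5.73) and *COI1* (-2.46) were also apart on Xcc replicate 1. A senescence-associated protein was apart on mock replicate 3 (-5.92), xylem cysteine proteinase 2 on Xcc replicate 4 (-5.65) and *ICS1* on mock replicate 1 (-0.13).

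Lists whose Xcc effect differed between times were flavonoids from 6 to 24 h (adjusted p = 8.5e-05), and phloem and epidermis with guard cells from 24 to 48 h (0.048 each), with adjusted p = 0.31, 0.67 and 0.90 with an estimated correlation. Of 64589 probes too dim to test, 215 were well above background on at least 3 Xcc arrays and no mock array at 6 h, with 183 the other way round. At 24 h these were 221 and 5, and at 48 h 9 and 136. Mock 24 h replicates 3 and 4, with the fewest probes above background among the 24 h arrays, enter the 24 h count.

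The first pattern weighed is the set of 131 probes at the floor on 6 arrays. Low overall signal is ruled out, since 99% of measurements of other probes of like level were well above background there, against 4.33% for these probes. A fault in an area of the slide is ruled out too: 6.87% of the probes had another of the set close by, under the 10.7% that random draws reach. With a gap of at least 1 log2 unit, 404 probes were low only on these arrays and 2 high only. That count holds the 131, and the arrays were picked by such probes, so it restates the pattern. Other alleles or missing genes in the plants of those 6 samples cannot be told apart from other causes. Sequencing of the same leaves would test them.

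The second is the comparison at 48 h, where 3 of 4 mock arrays and 1 of 4 Xcc arrays belong to those 6. With a term for the 6 arrays the median effect of the 130 called probes kept 96.1% of its size (1.29 before and 1.24 after, median SE 0.27 and 0.28) and 100% kept their direction, but only 10 probes were called with the term, 8 in both. A probe moved by the 6 arrays spreads widely within its groups and is then seldom called, so picking called probes largely fixed this outcome. The 6 arrays cannot be told apart from the treatment by it. Exchanging the replicate 4 arrays of mock and Xcc gives 6531 probes past the threshold. On the second principal component mock 48 h replicate 4 (-13) lay near Xcc replicates 1 to 3 (-29.2, -20.6 and 14.5). Xcc 48 h replicate 4 (124) lay among mock replicates 1 to 3 (126, 110 and 111). An exchange would give this, but so would the split between the 6 arrays and the others. On the first component mock replicate 4 (99.3) also lay near Xcc replicates 1 to 3 (99.7, 91.8 and 69.3). Xcc replicate 4 (37.6) lay nearest to mock replicate 3 (28.5), with mock replicates 1 and 2 at -28.1 and -37.1. There mock 6 h replicate 1 (-121) and Xcc 24 h replicate 4 (29.4), also of the 6, lay with their groups. The first component thus goes with an exchange more than with the split, and an exchange is not excluded. The chloroplast-encoded genes, a set chosen after the results were seen, cannot tell exchanged labels from a real difference. Their median difference is -0.17 between the replicate 4 arrays and -0.43 between the others. Of the 37 probes 51.4% have that sign in both, where over 80% would have excluded an exchange.

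The third is the likeness of the 6 h calls to the change of mock leaves from 6 to 24 h. Leaves further along the same course cannot be told apart from a response to Xcc. With separate mock arrays the share of the top 200 probes moving the same way ran from 55.5% to 88%. Weak signal on the mock 6 h arrays would not give the 70 calls that are higher in mock, which argue against it for those probes. For the 127 rises with Xcc it cannot be told apart. Of the tested probes 92.1% to 95.4% were well above background on the mock 6 h arrays and 90.9% to 98.4% on the Xcc 6 h arrays, ranges that overlap. A count of the 6 h calls against leaves sampled between 6 and 24 h would test the time course.

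The other ways of dividing the same arrays show whether chance can be excluded. At 6 h, 2 of 35 divisions gave at least the real count of 197, the highest other being 1640, for mock replicate 1 with Xcc replicates 1 to 3. Same-numbered mock and Xcc arrays correlate at 6 h (0.33, 0.16, 0.17 and 0.36), which the divisions do not take into account. The division with 1640 puts both replicate 1 arrays on 1 side. At 48 h, 4 of 35 gave at least 130, the highest other being 6531. Chance is not excluded for these 2. At 24 h and for the differences between effects the real count is 0, which every division reaches (35 of 35, and 100 of 100 for each difference), so the divisions say nothing about chance there. Their highest counts were 2 at 24 h, 737 (24 h less 6 h), 3268 (48 h less 24 h) and 6582 (48 h less 6 h). The large counts of other divisions point to structure in the samples. For mock leaves from 6 to 24 h only the real division, 1 of 35, reached the count (5570 against a highest other of 8). That is the lowest share 35 divisions can give. Chance is thus unlikely if the arrays are independent. Each slide held 1 group, so a difference between slides is not excluded. From 24 to 48 h it was also 1 of 35 (2380 against 1178). The divisions treat arrays as exchangeable, yet they sit 2 to a slide and 3 of 4 mock 48 h arrays are among the 6. The count was 2 with slide means and 12 with a term for the 6, so chance and structure in the samples are left open there.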

How the results depend on the processing

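Settings fixed beforehand come first, and the 4 chosen after the data were seen come in the paragraph that says so. Counts are probes past the threshold, and the cause of a change was not tested unless it is given. Main counts are 197 at 6 h, 0 at 24 h, 130 at 48 h, 0 in the 3 differences, 5570 and 2380 in mock leaves, 3 shared probes, and 4, 3 and 4 lists at 6, 24 and 48 h.

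Quantile normalization left 48 at 6 h, 4 at 48 h and 0 shared, with 5 lists at 24 h. The series matrix, scaled the same way, gave the same 48, 4, 0 and 5. Centring on the median gave 64 up and 170 down (2.3e+02 in all) at 48 h and 5 shared. Normexp left 51 at 6 h, 1 at 48 h, 127 in mock leaves from 24 to 48 h and 0 shared, with 8 lists at 6 h. It raised the median of all probes to 0.42 at 48 h, and with it 6 falls to positive values, 5 of them still below that median: At1g70700 0.17, the second ATP synthase beta probe 0.04, the 14-3-3-like protein 0.22, aspartate aminotransferase 0.38, the phytochrome A-associated F-box protein 0.54 and At1g52780 0.40. All 6 have no Xcc array well above background. An offset of 50 also shrinks differences between such low signals by construction.

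With no filter 8 were called at 6 h, 0 at 48 h (9780 at an unadjusted p under 0.05), 36544 for 48 h less 24 h, and 587 in mock leaves from 24 to 48 h, with 0 shared and 0 lists at 24 h. The lists then hold dimmer probes too, and at 6 h the medians of flavonoids and ethylene were -0.24 and -0.21 although both tests stayed up (adjusted p = 0.047 and 0.02); that of photosynthesis at 48 h was 0.07, its test staying down (adjusted p = 1.5e-08). Only probes well above background on all arrays gave 3457 and 964 in mock leaves, and 1 list at 48 h. One probe per gene gave 2782 and 944 in mock leaves, 5 shared, and 1 and 2 lists at 24 and 48 h.

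Slide as a random block (correlation 0.188) left 5 at 6 h, 0 at 48 h and 486 in mock leaves from 24 to 48 h, with 0 shared. The mean of each slide's arrays, 2 against 2, left 0 at 6 h (3276 at an unadjusted p under 0.05), 0 at 48 h (3144), 1943 and 2 in mock leaves and 0 shared; it has fewer degrees of freedom by construction. Position on the slide as a covariate left 37 at 48 h and 0 shared. Fitting only the groups compared gave 0 at 48 h (3378 at an unadjusted p under 0.05), 95 for 24 h less 6 h, 1 for 48 h less 6 h and 988 in mock leaves from 24 to 48 h.

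Replicate number as a block gave 473 at 48 h and 11 shared, and 229 at 6 h. It kept 29 of the 32 called genes named at 6 h and 24 of 24 at 48 h. In the pairing check 4 of 12 same-numbered mock and Xcc arrays correlated over 0.1, all at 6 h (0.33, 0.16, 0.17 and 0.36), and at 48 h these correlations ran from -0.71 to -0.17. Only 4 arrays correlated best with their own number, so pairing was not seen beyond 6 h. At 48 h the 6 arrays that stand apart include mock replicates 1 to 3 and Xcc replicate 4, which by itself makes same-numbered arrays differ. At 24 h they include Xcc replicate 4. The check therefore cannot tell whether the numbers mark pairs at those times.

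Chosen after the data were seen, the 75th percentile over all probes gave 88 up and 17 down (1.1e+02 in all) at 6 h, 3 at 48 h, 7592 in mock leaves from 24 to 48 h, 0 shared and 7 lists at 6 h. Without the 6 arrays that stand apart there were 3036 at 6 h, 2 at 48 h, 86 for 24 h less 6 h, 1 for 48 h less 24 h, 9 for 48 h less 6 h, 324 in mock leaves from 24 to 48 h and 0 shared. Mock 48 h is then replicate 4 alone, its spread taken from other groups, so the values that use it test nothing. A term for those arrays gave 495 at 6 h, 10 at 48 h and 12 in mock leaves from 24 to 48 h. Without the slide of mock 24 h replicates 3 and 4 there were 2496 and 43 in mock leaves.

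Leaving out each array in turn gave 3 to 1327 at 6 h, 0 to 0 at 24 h and 0 to 3759 at 48 h. The differences ran from 0 to 11 (24 h less 6 h), 0 to 446 (48 h less 24 h) and 0 to 9 (48 h less 6 h), and mock leaves from 4259 to 5345 and 483 to 4948. Shared probes ran from 0 to 250, and lists from 3 to 7, 2 to 5 and 2 to 6 at 6, 24 and 48 h.

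Trend and robust eBayes gave 221 at 6 h and 93 at 48 h, and kept 31 of the 32 and 20 of the 24 called genes named. A 2-fold threshold left 172 and 112. Keeping spots marked by the scanner software changed little (192 and 127). Of the lists, flavonoids and photosynthesis at 6 h stayed past the threshold in all 26 settings with the preset correlation, and abscisic acid at 48 h in 18. With an estimated correlation they had adjusted p = 0.55, 0.55 and 0.63. Probes near background are limited by the signal over it, since a subtraction or an offset then sets their log2 change.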

Other observations

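The sets of this part were chosen after the results were seen. Hypothesis 1 is that the whole pathway of methionine-derived glucosinolates is higher in Xcc leaves at 6 h. Its 11 probes, assigned by name or locus, had a median log2 change of 4.76 (-0.44 to 5.74), with 9 higher and 6 called up. The set was built around 4 genes among the largest rises, so a test of all 11 only restates them. Without the 5 probes of those genes the other 6 had a median of 0.93 and 1 call (camera p = 0.0083, and p = 0.15 with an estimated correlation), which does not carry the hypothesis to the whole pathway. The call was Supershoot 1 (B_1053879), which rose by 4.82 (limma adjusted p = 0.0167) from a mock 6 h mean of -7.83. Of the 6, 4 were higher and 2 lower. A second probe of branched-chain amino acid aminotransferase 4 (B_1054854) rose by 4.76 (adjusted p = 0.0274). At 24 h all 11 lay lower with Xcc (median -1.51, 0 called, p = 3.2e-05, and p = 0.11 with an estimated correlation), and at 48 h the median was 1.16 (p = 0.12, and 0.54 with an estimated correlation), or 1.41 with a term for the 6 arrays that stand apart. In mock leaves from 6 to 24 h limma called 7 of its probes up, with a median of 4.59 (camera p = 3.9e-05, and 0.12 with an estimated correlation), so a shift in timing would give the same rise as an induction by Xcc. Over the scalings the 6 h median of the 11 ran from 1.39 (normexp) to 4.84 (75th percentile over all probes), and it was 5.28 without the 6 arrays. Measuring these transcripts every few hours in both treatments would separate the 2.

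Hypothesis 2 is that transcripts of chloroplast-encoded genes are lower as a set at 48 h. Of its 37 probes, 25 were lower and limma called 8 down. The median was -0.35 (-2.56 to 0.63), with a camera p = 5e-06 and p = 0.16 with an estimated correlation. The set as a whole is thus not past the test, although *matK* (B_1049466) fell by 1.25 (adjusted p = 0.0486) and NADH dehydrogenase subunit 1 (B_1059768) fell by 1.47 (0.0422). Other probes of the same genes went the other way: *matK* B_1059745 was at 0.63 and ycf3 B_1064354 at 0.59. The 48 h median was -0.30 under quantile normalization, -0.42 with centring on the median, -0.75 with the 75th percentile over all probes and -0.26 under normexp. The medians of all probes were -0.21, -0.06, -0.40 and 0.42, against 0.01 with the scaling used, so the set lay only a little below them under quantile normalization. With a term for the 6 arrays that stand apart it was -0.39. At 24 h the median was -0.27 (p = 0.0014, and 0.32 with an estimated correlation), and with the 75th percentile over all probes it was 0.27 against 0.49 for all probes, still lower (p = 0.03). Random-primed or strand-specific sequencing would test it, since the labelling used here starts from poly(A) tails.

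Across genes, which are not independent, the log2 changes with Xcc correlate at 0.43 between 6 and 48 h, 0.04 between 6 and 24 h and -0.15 between 24 and 48 h. The 6 arrays that stand apart hold 1 mock array at 6 h, 1 Xcc array at 24 h, and 3 mock and 1 Xcc arrays at 48 h. That imbalance can by itself raise the 6 and 48 h correlation and lower the 24 and 48 h one. These values therefore do not show a response shared between times. Arrays with single-array patterns stand out as well: 220 probes were low only on Xcc 24 h replicate 4, 196 high only on mock 24 h replicate 4 and 59 high only on Xcc 48 h replicate 1. Each of these arrays enters the comparison at its own time.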
